A study of Caenorhabditis elegans with 2 samples.

How the data were processed

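The data were chromatin immunoprecipitation followed by sequencing (ChIP-seq) from 2 biological replicates of early C. elegans embryos in which PES-1 carried a fluorescent protein tag. Per the labels, chromatin came from whole organisms and was fragmented by sonication, and the sample descriptions name an antibody against the fluorescent protein for the immunoprecipitation, while the antibody field names pes-1, the tagged factor. The files used were lists of peaks. Per the deposited file lists, the assembly was ce11, both replicates were set against 1 shared control file, and reproducibility was assessed by the irreproducible discovery rate (IDR), the estimated share of peaks that would not recur between replicates. The aligner, the peak caller, their versions, any filter on mapping quality and read depths are not given in the sources used here. Signal tracks and alignments were not analysed here.

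Each list gives a score per peak, which in the deposited lists is the IDR rescaled to whole numbers. The deposited signal is the value that the peak caller gave each peak and is the authors' own. It was used to rank peaks and to describe them within a list, and no scaling between replicates is stated. The deposited ranked lists also give the -log10 of the global IDR per peak, and the deposited narrow peak format gives the position of the summit as an offset from the peak start. The ranked lists hold 8 further columns with values of the compared lists but no names, and these were not used. The conservative list compares the replicates with each other, the optimal list is derived from both replicates, and each replicate has its own list. The design assumed a deposited threshold of 0.05 on the IDR. The lowest deposited score was 830 and the lowest -log10 global IDR was 2.00 in the thresholded lists, so the threshold applied was 0.01. The planned stricter value of 0.01 therefore removed no peak, and 0.001 was added after the data were examined. The thresholded lists name 1 more parent file than the ranked lists do, and its content is not stated. They lack some ranked peaks that pass the threshold.

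Mitochondrial peaks were set aside, and summits within 200 bp of a stronger summit were merged into it. Summits of the full ranked lists were not merged. Promoters were windows from 1000 bp upstream to 200 bp downstream of transcript 5' ends of protein-coding genes in Ensembl release 115, and the genome sequence was the RefSeq copy of WBcel235, which is the same assembly as ce11. Summits were assigned to promoter, exon, intron and intergenic classes in that order. Shares were compared with shares of nuclear bases by two-sided exact binomial tests, with Benjamini-Hochberg adjustment over 4 classes, 6 chromosomes or 10 gene biotypes. Motifs were searched on both strands within 50 bp of the summit and in a window of the same size centred 500 bp away on 1 side drawn at random, and were compared by the two-sided exact McNemar test, adjusted over 11 motifs. The side was drawn once per set of peaks, so a subset has other flanks unless its sides are said to be kept, and 100 draws, including the one used, were compared after the data were seen. Words of 7 bp were compared likewise where at least 10 windows held them. Gene lists were compared with all other protein-coding genes by the two-sided Fisher's exact test, adjusted over 23 lists. An adjusted p of 0.05 was the threshold throughout. Intervals of shares, and of shares over a fixed expected share, are 95% Wilson intervals. Those of the ratio between groups of tRNA genes and of the forkhead ratio at weaker peaks are 95% intervals from a normal approximation on the log scale. Tests over peaks or genes treat these as independent and describe this set of peaks. They do not test a difference between samples. Signal in each replicate was taken from the nearest summit within 200 bp in that replicate's own ranked list.

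Genes were named by a rule fixed before the data were examined, as were the lists, tests and most alternatives: pes-1 and fkh-2, the gene with the nearest protein-coding 5' end within 2000 bp of each of the 20 strongest peaks, and up to 4 members per list with the strongest promoter peaks. The histone genes his-24 and his-72, the tRNA, snoRNA, spliced leader and microRNA genes, and the comparison by biotype were chosen after the values were seen. Names of tRNA genes came from the RefSeq annotation, WormBase release 298.

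Alternatives were the optimal set, stricter IDR values, each replicate's own set, other merging, overlap, promoter and motif windows, other backgrounds, and lists stratified by the distance to the next gene upstream. The procedures were tested on simulated data. With 1440 random summits and 100 draws, 0.75% of class tests and 0.182% of tests of the 11 motifs passed. Random summits were placed evenly over the genome, so they did not differ systematically from their flanks in base composition, as the real summits do. The rate for motifs need not hold for the real summits. GTAAACA planted in 5% of windows was called in 100% of 20 draws among the 11 motifs. Smaller shares, such as the 1.25% found at the conservative summits, were not planted. A list of ribosomal protein genes drawn at 8 times the rate of other genes was called in 100% of 20 draws among the 23 lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.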

Results

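Chromatin bound by PES-1 was profiled in early embryos of Caenorhabditis elegans, 1 hour after eggs were isolated by bleaching. PES-1 is a forkhead transcription factor, and its gene carried an epitope and green fluorescent protein tag inserted by CRISPR at the endogenous locus, so that an antibody against the fluorescent protein could be used for chromatin immunoprecipitation. The labels define 1 group of 2 biological replicates. There is no second condition, and the questions the design poses are where the tagged protein was recovered in the genome and how far the replicates shared those places. Read depth was not analysed here, so the intervals given below cover the counting of peaks and not the sampling of reads. Coordinates are those of the ce11 assembly.

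The list of peaks that passed the IDR threshold between the replicates, called the conservative set below, held 1452 peaks, which reduced to 1440 distinct summits. Such peaks need not be in either replicate's own thresholded list. Replicate 1 on its own gave 1041 peaks and replicate 2 gave 1164, a ratio of 1.12, and the optimal set, derived from both replicates, held 1793. Of the 1016 distinct nuclear summits of replicate 1, 682 (67.1%, 95% Wilson interval 64.2 to 70.0%) lay within 200 bp of a summit of replicate 2. Counted from replicate 2, 682 of its 1145 summits (59.6%, 56.7 to 62.4%) lay within 200 bp of a summit of replicate 1. Random placement on the same chromosome gave 0.446% on average for replicate 1 over 100 draws and 1.08% at most. Across 1402 conservative peaks found in both replicates' ranked lists, the deposited signal correlated with Spearman's rho = 0.754 and Pearson's r = 0.90 on the log2 scale. These peaks had been selected for reproducibility between the replicates, and over all 47814 ranked peaks found in both, rho was 0.313 and r was 0.36. These are correlations across peaks, which are not independent replicates. The replicate 2 signal was higher by a median of 0.32 log2 units, with an SD of 0.40 across peaks.

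**Figure D1:**
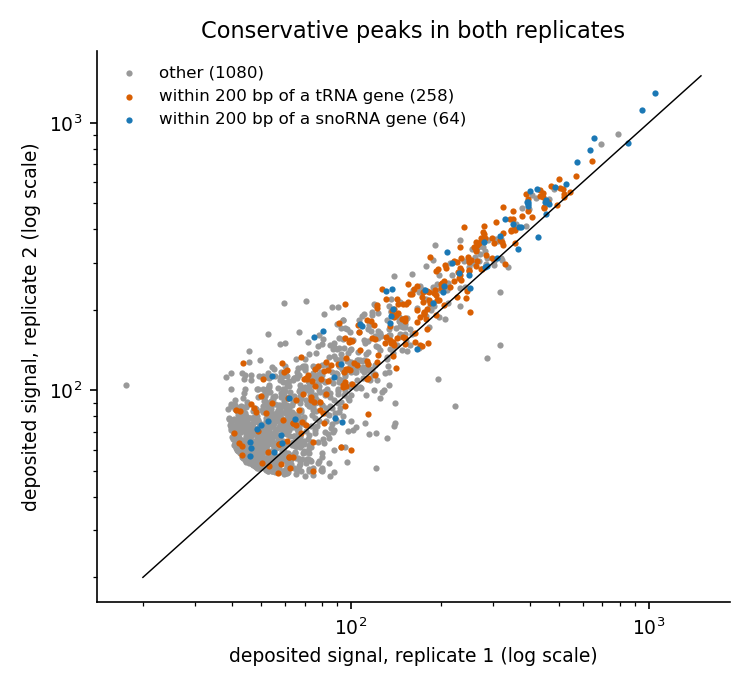
Deposited signal of each conservative peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with 1 point per peak found in both ranked lists and the line of equal signal. Orange points lie within 200 bp of a tRNA gene, blue points within 200 bp of a snoRNA gene and grey points near neither, and the orange and blue points fill the upper end, where 42 of the 50 strongest conservative peaks lay near such a gene.

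Within the conservative set, the strongest peaks lay at small noncoding RNA genes. That list leaves out ranked peaks with higher signals, up to 6830 against 2346 for its strongest peak. These left-out peaks are described below. Of the 20 strongest conservative peaks, 9 lay within 200 bp of a tRNA gene, 8 within 200 bp of a snoRNA gene (snoRNAs guide the modification of ribosomal RNA) and 1 beside the microRNA gene mir-51. The strongest, at chromosome V 12303449 to 12303852 with a deposited signal of 2346, lay in an intron beside the snoRNA gene C51F7.4. Its signal was 1054 in replicate 1 and 1297 in replicate 2, and the nearest protein-coding 5' end was that of F55C5.17. The next, at chromosome II 11960656 to 11961045 with a signal of 2056, was intergenic, beside the snoRNA gene W03C9.9 and nearest to W03C9.1. The other snoRNA peaks with a coding 5' end within 2000 bp were nearest to the chemoreceptor genes sre-23 (signal 1692) and str-56 (1438), to Y43F8C.7 (1113) and to T02E1.2 (1073). The tRNA peaks nearest to coding genes lay by C04A11.5, the collagen gene col-181, the cyclin E gene cye-1, the sorting nexin gene snx-17, the guanylyl cyclase gene gcy-33 and lev-9, which acts in acetylcholine receptor clustering, with signals from 1063 at lev-9 to 1359 at C04A11.5. A peak at chromosome III 8678398 to 8678717 (signal 1062) covered the tryptophan tRNA gene sup-5. Among these 20 peaks, those at K12H4.5 (chromosome III 8043814 to 8044117, signal 1698) and at atx-2, the ataxin-2 gene (chromosome III 10461175 to 10461462, signal 1037), were promoter peaks without an annotated small RNA gene within 200 bp.

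Over the whole conservative set, 266 of 1440 summits (18.5%, Wilson interval 16.6 to 20.6%) lay within 200 bp of a tRNA gene, against 0.272% of genome bases, and 282 of 612 nuclear tRNA genes (46.1%, 42.2 to 50.04%) had such a summit. For snoRNA genes the count was 65 summits (4.51%, 3.56 to 5.71%), a 24.8-fold excess over the genome share (exact binomial test, adjusted p = 1.13e-65), at 65 of 346 genes. That excess was 14.3-fold within 500 bp, 46.2-fold at an irreproducible discovery rate (IDR) of 0.001 and 4.40-fold for the 3 summits inside a snoRNA gene (exact binomial test, adjusted p = 0.0456). Summits at tRNA genes lay inside the gene in 238 of 266 cases, a median of 21 bp from its 5' end. Summits at snoRNA genes lay upstream of the gene in 58 of 65 cases, at a median position of -45 bp relative to the 5' end. The 2 classes together took 73.6% of the strongest 10% of peaks and 6.94% of the weakest 10%. This comparison and its alternatives were chosen after the data were examined, and 469 of the 612 tRNA genes have an identical copy elsewhere in the genome, so that peaks at single tRNA genes are uncertain.

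Relative to protein-coding genes, peaks were concentrated in promoters and scarce in exons. Promoter windows, from 1000 bp upstream to 200 bp downstream of an annotated 5' end, held 644 of 1440 summits (44.7%, 42.2 to 47.3%) against 26.3% of genome bases, a 1.70-fold excess (exact binomial test, adjusted p = 5.18e-51). Exons outside those windows held 54 summits (3.75%, 2.89 to 4.86%) against 21.7% of bases (0.173-fold, exact binomial test, adjusted p = 6.65e-84). Introns held 27.4% of summits against 27.1% of bases and intergenic sequence 24.1% against 25.04%, and neither passed the test (exact binomial test, adjusted p = 0.744 and 0.572). Both fell below the genome share once 5' ends of all annotated genes counted as promoters (0.568-fold for introns and 0.631-fold for intergenic sequence), and likewise without the summits near tRNA and snoRNA genes (0.863-fold and 0.846-fold).

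**Figure D2:**
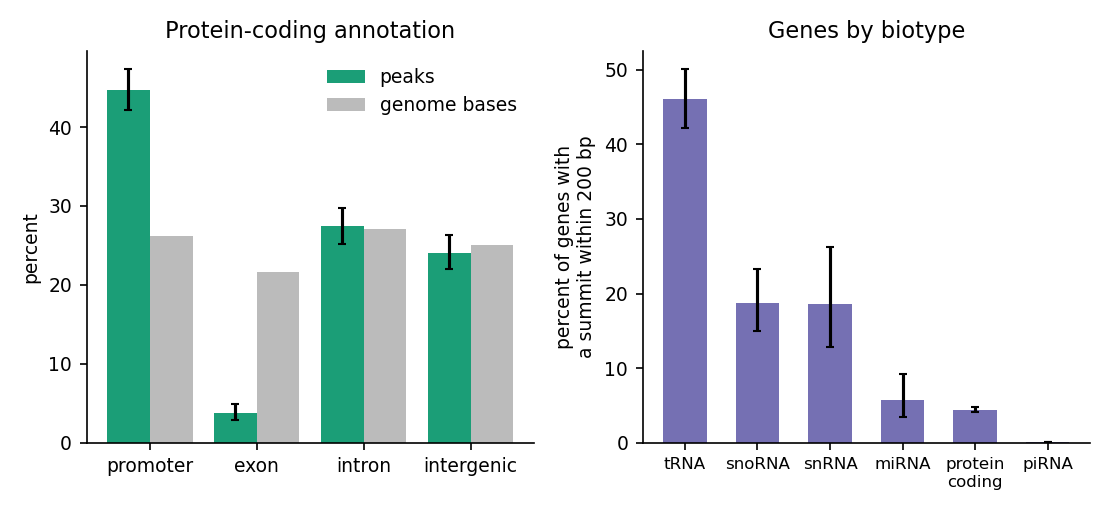
Left, the percent of the 1440 conservative summits (green, with 95% Wilson intervals) and of nuclear genome bases (grey) in each class of protein-coding annotation. Right, the percent of genes of each biotype with a summit within 200 bp, with 95% Wilson intervals, from 46.1% of tRNA genes to 0.104% of piRNA genes.

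Peaks were unevenly spread over the chromosomes. Chromosome III held 285 summits, 1.44 times its share of bases (exact binomial test, adjusted p = 7.03e-10), and chromosome V held 198, or 0.659 times its share (exact binomial test, adjusted p = 2.47e-11). Chromosome I held 261, or 1.21 times its share (exact binomial test, adjusted p = 0.00265), and this call was lost without replicate 2 (1.05-fold, exact binomial test, adjusted p = 0.547) and at an IDR of 0.001, an alternative chosen after the data were examined (1.14-fold, exact binomial test, adjusted p = 0.234). Chromosomes II, IV and X did not pass. Without the summits near tRNA and snoRNA genes, an alternative chosen after the data were examined, chromosome X held 0.612 times its share (exact binomial test, adjusted p = 9.67e-10). Of the 266 summits near tRNA genes, 115 were on chromosome X, which carries 276 of the 612 tRNA genes.

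The forkhead core site was rare at the summits. GTAAACA or its reverse complement lay within 50 bp of 18 of 1440 summits (1.25%, 0.792 to 1.97%) and in 11 flanking windows 500 bp away (0.764%, 0.427 to 1.36%), a difference that did not pass the test (exact McNemar test, adjusted p = 0.291). Against the other flank of the same summits the ratio fell from 1.64 to 0.783. These equal the highest and the lowest ratio in 100 draws of the flank side, whose median was 1.06, and GTAAACA passed in 0 of them. The degenerate site RYAAAYA was less frequent at summits than in flanks (11.4% against 15.5%, exact McNemar test, adjusted p = 0.00346), as were the GATA site HGATAR (12.8% against 24.2%, adjusted p = 4.69e-14 by the same exact test) and the homeobox site TAATTA (1.32% against 5.35%, adjusted p = 4.01e-09 by the same exact test). GAGAGA was more frequent, at 12.4% of summits against 5.83% of flanks (exact McNemar test, adjusted p = 4.39e-09). The E-boxes CACGTG and CATATG, the T-box site TCACACC, the bZIP sites TTGCGCAA and TGACGTCA, and the arbitrary word GTGTTG did not pass. Base composition was not controlled in these tests. Summit windows held 49.7% G and C and flanks 36.96%, so sites rich in A and T may be rarer at summits for that reason. Drawing other flanks does not remove this limit, and a comparison with shuffled summit windows is reported for GTAAACA alone. Some of the motif calls depend on which flank was drawn. Over 100 draws, tested after the data were examined, HGATAR, TAATTA and GAGAGA passed in 100, RYAAAYA in 91, TTGCGCAA in 26 and each of the others in 12 or fewer. Without the summits near tRNA and snoRNA genes and with the flank sides kept, RYAAAYA was 0.739 times as frequent at summits as in flanks (exact McNemar test, adjusted p = 0.0137), and TTGCGCAA passed (9 windows against 1, exact McNemar test, adjusted p = 0.0473), as it did in 70 of 100 draws. At an IDR of 0.001 with the sides kept, RYAAAYA was at 0.703 times (exact McNemar test, adjusted p = 0.0443), TGACGTCA passed (0 summit windows against 7, exact McNemar test, adjusted p = 0.0443) and GAGAGA, at 1.55 times, did not (exact McNemar test, adjusted p = 0.0517), although it passed there in 71 of 100 draws at a median of 1.71 times. When the sides were drawn anew in these subsets, RYAAAYA passed in neither, at 0.783 times in the first (exact McNemar test, adjusted p = 0.0523 and 0.058). TCACACC passed in the first (exact McNemar test, adjusted p = 0.00134) and CATATG in the second (adjusted p = 0.0494 by the same exact test). Over 100 draws they passed there in 14 and 50. With the sides kept, neither TCACACC nor CATATG passed there (exact McNemar test, adjusted p = 0.0645 and 0.0707). Without replicate 2 the RYAAAYA call was lost (exact McNemar test, adjusted p = 0.339), and without replicate 1 the arbitrary word GTGTTG passed (exact McNemar test, adjusted p = 0.00464), each with its own draw.

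A search over 7679 words of 7 bp found 1020 more frequent at summits and 885 more frequent in flanks (1002 to 1041 and 822 to 917 over 20 draws of the flank side). The first was GGTTCGA, the core of the internal B box of tRNA promoters, in 181 summit windows (12.6%) and 13 flanking windows (exact McNemar test, adjusted p = 4.94e-37). The second, CGAACCC (99 against 8 windows), has the reverse complement GGGTTCG, which overlaps GGTTCGA. Many of the next words were rich in G and C, among them CTCGGCC (87 against 9) and CTTGCGC (62 against 2). The words most depleted were rich in A and T, such as TTAAAAA (59 against 221). Summit windows had 49.7% G and C on average and flanking windows 36.96%. Away from tRNA and snoRNA genes, 1109 summits remained, 552 words were more frequent at summits, and CTTGCGC led the list (exact McNemar test, adjusted p = 9.46e-14), although the first word changed with the draw of the flank side. Neighbouring words overlap, so these counts are not counts of separate motifs.

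**Figure D3:**
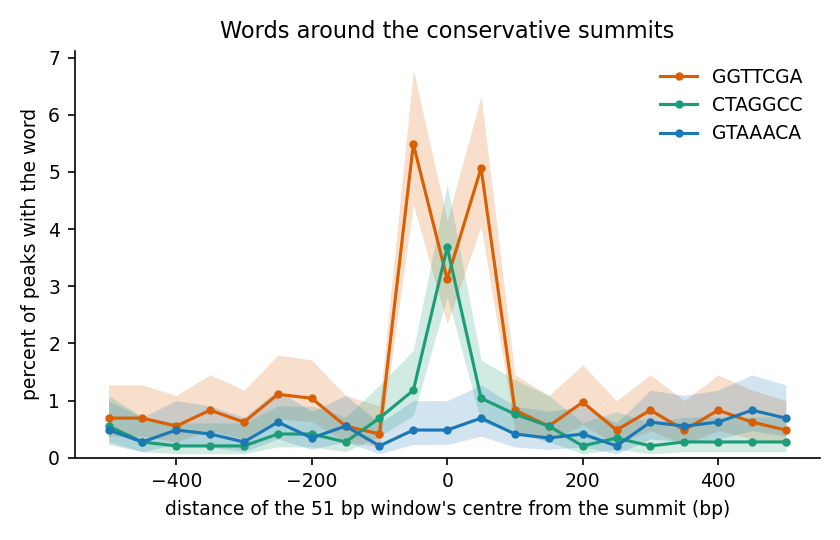
Percent of the 1440 conservative peaks (y axis) with a word or its reverse complement in a 51 bp window, by the distance of the window's centre from the summit in bp (x axis), with 95% Wilson intervals as shading. GGTTCGA is at 5.49% in the window at -50 bp and 5.07% at 50 bp, CTAGGCC is at 3.68% at the summit, and GTAAACA is at 0.486% at the summit.

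At protein-coding genes, promoter peaks were more frequent at histone, ribosomal protein and chaperone genes than at other genes, and less frequent at chemoreceptor genes. A promoter peak was present at 816 of 19973 protein-coding genes (4.09%). Among 23 gene lists fixed before the data were examined, 4 passed the test. Histone genes had a promoter peak in 27 of 72 cases (37.5%, Wilson interval 27.2 to 49.1%, odds ratio 14.5, Fisher's exact test, adjusted p = 3.95e-18). The odds ratio was 8.81 when stratified by the distance to the next gene upstream and 8.94 when each peak counted for its nearest gene alone, which left 15 histone genes. The 27 genes shared 18 peaks, since many histone genes stand in divergent pairs, and examples were his-67 and his-68 (1 shared peak, signal 408) and his-59 and his-60 (1 shared peak, signal 340). The list takes every his gene, and his-24, a linker histone, and his-72, an H3.3 variant, were among those with a peak. Ribosomal protein genes had a peak in 19 of 81 cases (23.5%, 15.6 to 33.8%, odds ratio 7.34, Fisher's exact test, adjusted p = 3.56e-09), led by rpl-3 (signal 608), rpl-15 (409), rps-24 (374) and rps-20 (336). Heat shock and DnaJ chaperone genes had a peak in 10 of 51 cases (19.6%, 11.0 to 32.5%, odds ratio 5.79, Fisher's exact test, adjusted p = 0.000197), led by dnj-29 (441), the mitochondrial chaperonin hsp-60 (315), dnj-28 (279) and dnj-13 (199). Without replicate 2, 5 of these genes had a peak and the call was lost (odds ratio 3.42, Fisher's exact test, adjusted p = 0.117). Chemoreceptor genes had a peak in 6 of 1309 cases (0.458%, 0.210 to 0.996%, odds ratio 0.102, Fisher's exact test, adjusted p = 3.52e-16), with sre-23, sre-1 (signal 550), sri-5 (314) and srh-269 (281) the strongest, and the sre-23 peak lay beside a snoRNA gene and the srh-269 peak beside a tRNA gene. The odds ratio was 0.185 without replicate 1 (9 genes), 0.159 without replicate 2 (7 genes), 0.165 with promoters from 2000 bp upstream to 500 bp downstream and 0.216 at an IDR of 0.001. For ribosomal protein genes it was 11.6 at that IDR, and both calls held throughout.

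**Figure D4:**
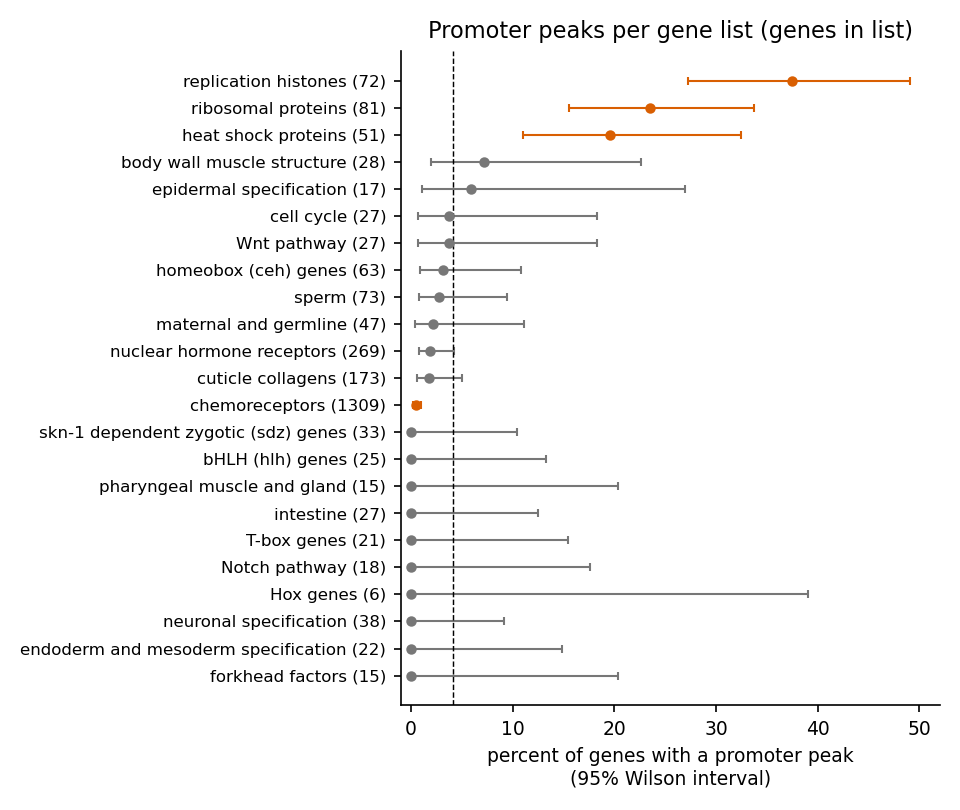
Percent of the genes of each list with a conservative peak in the promoter window (x axis), with 95% Wilson intervals, one list per line with its number of genes. Orange lists passed Fisher's exact test after adjustment over the 23 lists, grey lists did not, and the dashed line marks the 4.09% of all protein-coding genes.

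Promoters of developmental regulators held few peaks, as did those of all protein-coding genes (4.09%), and these lists did not pass the test. Neither pes-1 (chromosome IV 5002748 to 5005486) nor fkh-2, another forkhead gene (chromosome X 3740207 to 3742323), had a promoter peak, and none was listed in either promoter among the 74874 peaks of the full ranked list. The conservative peak nearest to the pes-1 5' end was 36193 bp away. No promoter peak was found for the 15 forkhead genes, the 22 endoderm and mesoderm specification genes, the 38 neuronal specification genes, the 6 Hox genes, the 21 T-box genes, the 18 Notch pathway genes, the 15 pharyngeal genes, the 27 intestinal genes, the 25 hlh genes or the 33 sdz genes. A count of 0 of 38 allows a share of up to 9.18% by the Wilson bound, and the 4.09% of all genes lies within the interval of each of these lists. Single members had a peak elsewhere: the GATA factor gene elt-6 (signal 119, 1 of 17 epidermal genes), the Porcupine homologue mom-1 (1063, 1 of 27 Wnt pathway genes), the cyclin-dependent kinase inhibitor cki-1 (131, 1 of 27 cell cycle genes) and the maternal gene mex-1 (310, 1 of 47). The mom-1 peak lay at a tRNA gene and was the lev-9 peak named above. The actin genes act-4 (111) and act-1 were the 2 of 28 muscle genes, and spe-48 (549) and spe-9 (368) the 2 of 73 sperm genes. Collagen genes had a peak in 3 of 173 cases (col-185, col-71 and col-46), nuclear hormone receptor genes in 5 of 269 (led by nhr-255, nhr-41, nhr-47 and nhr-49) and ceh genes in 2 of 63 (ceh-2 and ceh-38). The peaks at spe-9, col-185, nhr-255, nhr-41 and ceh-2 also lay within 200 bp of a tRNA gene. The smallest adjusted p among these lists was 0.287 by Fisher's exact test, for the nuclear hormone receptors.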

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

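The tests of abundant transcription, of tRNA genes without shared words, of isolated tRNA genes of unique sequence, of mitochondrial peaks, of the share of summits in chromosome centres and of the forkhead site at peaks away from small RNA genes were chosen only after the results were seen. The design has 1 group, so no biological explanation was tested against another group.

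Data outside the main comparison held 22 mitochondrial peaks in the list of replicate 1, with a median deposited signal of 1061, and 18 in the optimal set. Replicate 2 had 0, even among the 75072 peaks of its full ranked list. By genome length that list would hold 10.3 mitochondrial peaks, which argues against chance. A difference between the replicates in mitochondrial DNA or in its filtering may account for it and was not tested, because reads were not analysed here.

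The conservative list leaves out 101 ranked peaks that pass its threshold. They include the strongest ranked peak, at chromosome X 15810936 to 15811232 with a signal of 6830. Only 9 of the 101 lay within 200 bp of a protein-coding, tRNA, snoRNA, snRNA or microRNA gene. By contrast, 68.45% of nuclear bases lie within 200 bp of a protein-coding gene, so the left-out peaks lay largely away from genes of these types. Other annotated types, such as pseudogenes and piRNA genes, were not examined for them.

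Peaks at tRNA and snoRNA genes are open to a technical reading. Random windows matched to the summits on G and C content lay within 200 bp of such a gene in 1.21% of cases, against 22.99% of summits (20.9 to 25.23%), which argues against base composition as the cause. Of 100 tRNA genes of unique sequence with no other tRNA gene within 1000 bp, 32% (23.7 to 41.7%) had a peak, against 0.698% (0.635 to 0.767%) of random windows of the same lengths, which argues against reads shared between identical copies as the whole cause. A part in the pattern stays open, since all 143 tRNA genes of unique sequence (30.07% with a peak) had one 0.590 times as often as those with an identical copy (0.453 to 0.769). Reads shared between copies that differ stay open as well. Only 21 tRNA genes share no 30 bp word with another, and 1 of them had a peak (4.76%, 0.8456 to 22.67%). That interval lies below those of genes with an identical copy (46.45 to 55.46%) and of unique sequence (23.16 to 38.03%). A low share is what reads shared between differing copies would give, but it rests on 1 gene with a peak and cannot decide. Whether these 21 genes differ from the rest in other ways was not tested. Recovery of abundantly transcribed chromatin without a forkhead site is a candidate explanation, in line with the odds ratio of 7.34 for ribosomal protein genes and the scarcity of peaks at chemoreceptor genes. GTAAACA lay in 18 of the 1440 summit windows but in 6 of the 1109 away from these genes. Most windows with the site thus lay near them. With the flank sides kept, flanks held it in 11 and 8 windows. With both flanks of each summit counted, the ratio was 1.06 over all summits and 0.462 over the 1109. Summits near these genes thus held the site more often than their flanks did. These counts are small and were not tested on their own. Transcription was not measured here. Binding of PES-1 at such genes, through that site or another route, cannot be separated from such recovery with peak lists alone.

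Chromosome V held fewer peaks than its length gives. In the central 33.3% of each chromosome alone the ratio was 0.721 (0.561 to 0.916), and over promoter windows without those of chemoreceptor genes it was 0.681 (0.563 to 0.818), against 0.618 over all promoter windows. Neither interval excludes a ratio of 0.8, the bound set before these ratios were computed, and each lies below 1. Over all chromosomes the central 33.3% held 24.9% of summits (22.8 to 27.2%), the reverse of what fewer peaks on chromosome arms would give, which argues against that explanation. A contribution of chemoreceptor families may remain.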

How the results depend on the processing

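The alternatives with an IDR of 0.001, without summits near tRNA or snoRNA genes, with the flank sides kept and with the other flank side were chosen after the data were examined, as was every alternative for peaks near tRNA and snoRNA genes. The excess at promoters and near tRNA and snoRNA genes passed its test in each alternative run, but for summits inside snoRNA genes only narrowly (3 summits, 4.40-fold, exact binomial test, adjusted p = 0.0456). The number of gene lists passing was 4 in each alternative except 3 without replicate 2, and the number of chromosomes passing ranged from 2 to 4. The planned IDR of 0.01 equals the deposited threshold and so changed no value. Leaving it out, 348 alternatives were run for single classes, chromosomes, motifs, lists and named peaks, of which 329 stayed the same, 7 calls were lost and 12 were gained. Tests stayed the same on one side of the threshold, while counts of named peaks had no test and were judged against the main count. The 10 lists without a promoter peak could hardly pass on the low side, since even 0 of 38 gave p = 0.406 by Fisher's exact test. Their stability carries little weight.

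The forkhead ratio, 1.64 in the main analysis, fell to 1 or below in 11 of 14 alternatives, and no alternative that searched GTAAACA passed. It was 0.895 in the optimal set, 1 at an IDR of 0.001 (1.25 with the flank sides kept), 0.546 without summits near tRNA or snoRNA genes (0.75 with the flank sides kept), 1 within 25 bp, 0.906 within 100 bp, 0.75 against random promoter windows and 0.783 against the other flank side, and it stayed at 1.64 with flanks 300 bp away. It ranged from 0.65 to 0.938 when a replicate was left out, and the degenerate site RYAAAYA gave 0.735. Against a shuffle that keeps the dinucleotides of the summit windows, and so their base composition, it was 2.25 and did not pass (exact McNemar test, adjusted p = 0.208). The draw of the flank side alone moved it from 0.783 to 1.64 over 100 draws, with a median of 1.06, so the main ratio is the highest of them.

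An IDR of 0.001 left 608 summits and 396 genes with a promoter peak, by construction a smaller set. Without summits near tRNA or snoRNA genes, 552 words were more frequent at summits (557 with the flank sides kept), fewer than the 703 from the 608 summits at an IDR of 0.001, so the number of peaks alone does not account for it. A reciprocal overlap of 50% counted 57.0% of replicate 1 peaks as shared. The rank correlation was 0.688 in the optimal set, 0.660 without the 10% strongest peaks and 0.313 over all ranked peaks, and the cause was not tested. No paired analysis was possible because there is 1 group. Read depth, unknown here, limits which weak peaks could be called.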

Other observations

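The tests in this part were chosen after the data were first examined, except the comparison with shuffled windows, and of these the test on weaker peaks alone had its bound set before its result was seen. The excess at tRNA genes was spread over the isotypes. The share of genes with a summit within 200 bp ran from 63.0% of 27 aspartate tRNA genes and 61.5% of 13 cysteine tRNA genes to 37.04% of 27 glutamine tRNA genes among the standard isotypes, and no isotype passed Fisher's exact test against the others (smallest adjusted p = 0.861). Small nuclear RNA genes had a summit in 24 of 129 cases. Among these, 7 of 18 annotated genes for the SL2 spliced leader, which is joined to downstream genes of operons, had one, and 0 of 12 genes for the SL1 spliced leader did. That contrast was not tested, and sequence shared between copies of the spliced leader genes was not examined. Of 261 microRNA genes, 15 had a summit within 200 bp (5.75%), from 11 summits. Among them, 4 of the 7 genes mir-35 to mir-41 and 3 of the 6 genes mir-51 to mir-56 had one, and both groups were picked after their values were seen. Several genes can share a summit, and the summits per group were not counted. Genes for piRNAs were scarce near summits, with 16 of 15363 within 200 bp.

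Peaks lay away from chromosome centres. The central 33.3% of the chromosomes held 24.9% of summits (22.8 to 27.2%) (exact binomial test, p = 4.46e-12) and 37.1% of promoter windows, and 22.5% of the 1109 summits away from tRNA and snoRNA genes. In 8 lists of developmental regulators pooled after the data were examined, 2 of 154 genes had a promoter peak (1.299%, 0.357 to 4.61%) against 4.11% of other genes, which did not pass Fisher's exact test (p = 0.0977).

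The hypothesis that peaks away from tRNA and snoRNA genes reflect binding through the forkhead core site was tested on the 1109 such summits. GTAAACA lay in 0.541% of their windows (0.248 to 1.18%), against 0.992% of flanks (exact McNemar test, p = 0.332, ratios from 0.316 to 0.857 over 100 draws of the flank side), which argues against it for most of these peaks. The same hypothesis was tested on the weaker peaks of the full ranked list, those ranked after the first 1500, of which 73039 lay away from such genes. GTAAACA was 0.818 times as frequent at their summits as in flanks (0.731 to 0.915), below the 1.2 the hypothesis asked for. This is the lowest ratio in 100 draws of the flank side. The median was 0.877 and the highest 0.943, so the ratio stayed below 1.2 in each draw, while the exact McNemar test gave p under 0.05 in 76 of them. Of all 74874 ranked peaks, 1553 passed the IDR threshold, and the replicates' rank correlation over matched ranked peaks was 0.313. Most of the weaker peaks did not pass, and sites at reproducible ones may be diluted. Summits of the ranked list were not merged, so their windows may overlap and some flanks may lie at other ranked peaks. The interval and the test treat these windows as independent. The ratio therefore describes the weaker peaks as a whole and cannot decide for real sites among them. The flanks of the conservative summits are poorer in G and C than those summits, and base composition was not measured for the weaker peaks. Against shuffled summit windows with the same dinucleotides, the ratio over all conservative peaks was 2.25, which did not pass (exact McNemar test, adjusted p = 0.208). RYAAAYA was 0.783 times as frequent at the 1109 summits as in flanks (exact McNemar test, adjusted p = 0.0523), passing in 39 of 100 draws of the flank side, and 0.938 times on the weaker peaks. Binding through other sites may still occur.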
